A study of Mus musculus with 24 samples.

How the data were processed

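Liver RNA was sequenced from 24 mice of the CD2F1 strain in 3 groups of 8. Per the labels, CT mice were sham-injected, C26 mice carried the C26 colon carcinoma, a transplanted tumour that causes wasting (cachexia), and C26-CHO mice carried the same tumour and received cholestyramine, a resin that binds bile acids in the gut. The resin made up 2% of the diet by weight from day 1 to day 10 after cell injection. Each library comes from a separate mouse, numbered 1 to 8 within its group. The labels give no sequencing date, batch, sex or tumour weight.

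Per the labels' protocols, livers were frozen, RNA was extracted with Trizol, treated with DNase I and made into libraries with Illumina protocols. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.17, checked with FastQC, trimmed with Trimmomatic 0.38, aligned to the mouse genome build GRCm38 with STAR 2.6.1d and normalised with DESeq2 1.22.2. The counting tool, the gene annotation and the use of strand are not given in the sources used here. Reads of near-identical genes could therefore have been divided or dropped in counting, so values of Saa1 and Saa2, Cyp2a4 and Cyp2a5, the Cyp2c genes, Gsta1 and Gsta2, Orm2, Ces1f and Mt1 and Mt2 are uncertain as values of the single gene, as are genes that overlap an antisense gene.

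The deposited table holds 22392 genes for 24 libraries, and no column was left unused. The authors deposited a normalized signal, which is the gene count of each library divided by a size factor of that library. Every value is a whole multiple of the smallest value above 0 of its column, for 100% of values within a tolerance of 0.001 of a read, and the largest distance from a whole number was 6.3e-09. Size factors computed anew from the recovered whole reads with the DESeq2 median-of-ratios method differed from these steps by at most 5.4e-15 in relative terms. The number of reads behind each value is therefore known. The table lists no gene with fewer than 5 reads over all libraries. A symbol was found for 21959 gene identifiers and not for 433, which held 0.137% ± 0.0275 (SD, n = 24) of the reads. Coordinates and gene types were taken from GENCODE M21, which is on GRCm38.

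Recovered reads ranged from 19.9 M to 30.5 M per library. Cholestyramine libraries were the deepest, with a mean of 25.8 ± 3.50 M (SD, n = 8) against 22.8 ± 2.90 M in C26 and 22.02 ± 1.10 M in CT. Counting error alone does not describe the spread between mice: within groups, chi-square per degree of freedom between libraries ran from 6.97 to 193.59 over pairs of libraries, on genes with at least 20 reads in the pair.

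Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend) on log2 of the deposited value plus 1. A gene was kept when its mean deposited value over the 24 libraries was at least 10, which left 14040 genes. All 24 libraries entered a single fit with the 3 groups and no covariate, and each of the comparisons C26 vs CT, C26-CHO vs C26 and C26-CHO vs CT was a contrast of that fit. A gene was called when its Benjamini-Hochberg adjusted p, within the contrast, lay under 0.05. Adjusted p values of single genes are from this limma test unless another tool is named. Fold changes are given on the log2 scale with the standard error (SE) of the fit, and group levels as the mean deposited value ± SD over 8 mice.

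Gene lists were written from textbook knowledge of liver biology: 40 lists, of which 37 had at least 5 tested members. The lists of T and NK cell, pancreatic acinar and intestinal epithelium markers had fewer and were not tested. Lists were tested with camera of limma, two-sided, with a preset correlation between genes of 0.01 and adjustment over the 37 lists; the test was repeated with the correlation estimated from the data and with fry. For each list, members were also counted with p adjusted over the list alone. Because camera compares a list with all other genes across strongly correlated genes, an exact two-sided permutation test of the list's mean log2 value per mouse was added after the data were seen, with adjustment over the 37 lists; with 8 mice against 8 its smallest p is 0.000155.

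Genes named in the text follow a rule. For each comparison these are the 8 called genes with the largest rise and the 8 with the largest fall among genes with a mean value of at least 50 and a symbol that is not a predicted or clone name; up to 4 members with the smallest p of each list described; and 17 genes of bile acid, sterol and acute phase biology named in every comparison. Because the first and last of these already name about 30 genes in a comparison, few list members are named. Some genes that this rule selects are not reported here. Any other gene is said to have been chosen after its values were seen. The rule, the lists, the main test and the alternatives were fixed before the data were examined, except where the text says otherwise.

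Genes moved back by cholestyramine are those called in C26 vs CT and called in the opposite direction in C26-CHO vs C26. Since both contrasts use the C26 libraries, the correlation and covariance of their fold changes were also computed in 100 simulations of unchanged groups that share libraries in the same way, and with the shared libraries split into replicates 1 to 4 and 5 to 8. The same was done for the contrasts that share CT.

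The procedure was tested on simulated counts drawn from the real means and library sizes of the 14040 genes, with 200 genes changed. In the simulation of C26 vs CT it recovered 76.1% of 67 genes changed 1.5-fold, 89.6% of 67 changed 2-fold and 100% of 66 changed 4-fold, and 4.3% of its calls were false. In that of C26-CHO vs C26 it recovered 71.6%, 97% and 100%, with 2.2% false. In that of C26-CHO vs CT it recovered 70.1%, 91% and 100%, with 4.4% false. Genes were drawn independently of each other and no mouse stood apart, unlike in the real data. These shares therefore do not give the error rate of the real comparisons.

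Alternatives were a pseudocount of 0.5 or 5, no filter on low values or a mean of at least 50, only the 2 groups compared, TMM rescaling, quantile normalization, limma library weights, the replicate number as a block, edgeR 4.0.16 quasi-likelihood tests on the recovered reads with TMM or RLE factors, DESeq2 1.42.0 on the recovered reads, and each library left out in turn. On the recovered reads, edgeR with TMM called 117 genes in C26-CHO vs C26. Leaving out C26-CHO 1 and C26 8 together was added after the data were seen. The lowest median log2 fold change of all genes under any scaling and comparison was -0.02. Groups of 8 values were searched for a library standing apart with Dixon's ratio (gap over range above 0.526). Tables, permutation tests and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.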

Results

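The liver transcriptome was measured by RNA sequencing in 24 mice: 8 sham-injected controls (CT), 8 mice carrying the C26 colon carcinoma (C26) and 8 C26 mice fed cholestyramine (C26-CHO). C26 is a transplanted mouse tumour used as a model of cancer cachexia. Cholestyramine is a resin that holds bile acids in the gut and so raises the demand on the liver for bile acid and cholesterol synthesis. Recovered reads per library averaged 22.02 ± 1.10 M in CT, 22.8 ± 2.90 M in C26 and 25.8 ± 3.50 M in C26-CHO (SD, n = 8 each). C26-CHO libraries were deeper than CT libraries by 3.77 M reads (exact two-sided permutation test, p = 0.0129, adjusted p = 0.0194 over 7 measures and 3 comparisons).

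The first principal component of the 14040 tested genes held 71.9% of the variance. It separated CT livers, with scores from -83.15 to -75.36, from C26 livers, with scores from 28.81 to 54.62. C26-CHO livers 2 to 6 and 8 lay within the range of the C26 livers at 34.54 to 50.48, C26-CHO 7 lay below it at 22.32, and C26-CHO 1 lay between the groups at -13.41.

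**Figure D1:**
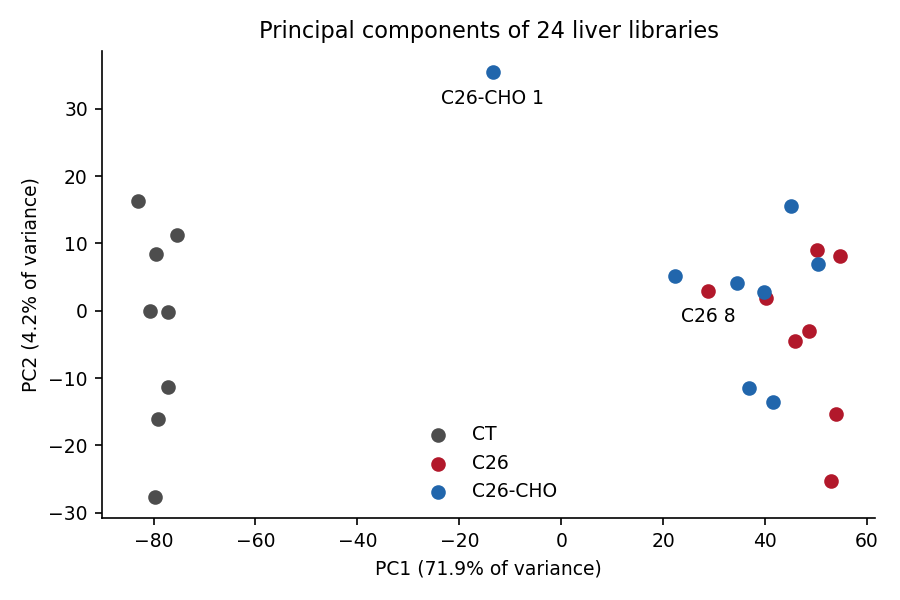
Scores of the 24 libraries on the first and second principal components of log2 values (axes without units, with the percent of variance each holds). Each point is a mouse, coloured by group. CT lies apart from both tumour groups on the first axis, and C26-CHO 1 lies between at -13.41.

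The first comparison, C26 vs CT, asks how the liver responded to the tumour. C26 livers switched to an acute phase pattern. The serum amyloid A genes Saa1 and Saa2, the iron-chelate binding protein Lcn2 and the protease inhibitor A2m, all secreted in inflammation, rose with log2 fold changes of 8.51, 8.98, 8.97 and 9.66. Genes of hepatocyte metabolism fell on the same scale: the drug-metabolising enzyme Cyp3a11 had -8.59, carbonic anhydrase Car3 -8.33, the carboxylesterase Ces1f -7.64 and the glutathione transferase Gsta2 -7.52. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, went from 5305 ± 1503 in CT to 87.1 ± 92.5 in C26 (mean ± SD, n = 8). Its log2 fold change was -6.37 (SE 0.608, adjusted p = 9.88e-10). Of 14040 genes, 9305 were called, 4681 higher and 4624 lower. At least 2-fold changes were found in 2439 of them, 1279 higher and 1160 lower.

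The acute phase list showed the largest median rise of the 37 lists. Of its 26 members 25 rose, and the median was 4.34 (camera adjusted p = 3.08e-21; adjusted p = 0.121 with an estimated correlation). The sole member to fall, Hamp, which encodes the iron hormone hepcidin and was chosen after its value was seen, had -0.67. These 26 genes took 30.9% ± 0.912 of all reads in C26 against 2.18% ± 0.139 in CT (SD, n = 8, exact permutation test, adjusted p = 0.000363). Albumin, Alb, the main plasma protein, went from 5.19% ± 0.307 to 0.991% ± 0.189 of reads (SD, n = 8, exact permutation test, adjusted p = 0.000363). Part of that fall in share follows from the acute phase genes taking more of the reads.

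Genes of IL-6 and STAT3 signalling, which drives acute phase transcription, rose in 12 of 15 cases, with a median of 1.67 (adjusted p = 1.12e-05; adjusted p = 0.121 with an estimated correlation). Socs3, a feedback inhibitor of that pathway, had 5.55 (SE 0.139, adjusted p = 2.43e-21), the oncostatin M receptor Osmr 4.08 and Stat3 1.73. Il1rap, chosen after its value was seen, fell with -1.02. Cytokine, chemokine and adhesion genes had 9 of 12 members higher (median 2.29, adjusted p = 0.00982; adjusted p = 0.463 with an estimated correlation), among them the neutrophil attractant Cxcl1 with 4.08. The 3 lower members, chosen after their values were seen, were the T cell attractants Ccl5 (-1.60), Cxcl9 (-3.73) and Cxcl10 (-1.32). Complement and coagulation genes had 14 of 25 members higher, including the complement protein C3 with 2.33 (median 0.33, adjusted p = 0.0017; adjusted p = 0.254 with an estimated correlation). The 5 lower ones, also chosen after their values were seen, were C6 (-0.46), C8g (-1.20), C9 (-0.40), F11 (-0.22, or 0.00 under quantile normalization) and Proc (-0.55). Of the genes of ER stress and the amino acid response 16 of 18 rose, including asparagine synthetase, Asns, with 6.10 (median 1.28, adjusted p = 5.43e-06; adjusted p = 0.217 with an estimated correlation). Herpud1, chosen after its value was seen, fell with -0.99.

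Among the largest rises outside these lists were the gut and pancreas lectin Reg3b (9.04, from 34 reads over all CT libraries), the acid phosphatase Acpp (8.02, from 19 reads), the proton pump subunit Atp6v0a4 (7.85, from 23 reads) and Igdcc4 (7.62). Among the largest falls were the P450 Cyp2c29 (-7.45), the steroid dehydrogenase Hsd3b5 (-7.34), the bile acid and organic anion carrier Slco1a1 (-6.95) and the methyltransferase Inmt (-6.89). Adjusted p for these 8 genes lay between 4.31e-16 and 2.59e-09.

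Bile acid genes fell as a group. Bile acid synthesis had 12 of 16 members lower, with a median of -0.63 (camera adjusted p = 0.000675; adjusted p = 0.231 with an estimated correlation). Besides Cyp7a1, Cyp8b1, which sets the cholic acid share of bile acids, fell with -3.61 (SE 0.314, adjusted p = 1.73e-10). Cyp27a1, the first enzyme of the alternative pathway, fell with -2.06 (SE 0.159, adjusted p = 2.06e-11), and Cyp7b1, its second enzyme, had -0.44 (adjusted p = 0.265). Cyp39a1 and Acox2, chosen after their values were seen, rose with 1.18 and 0.58.

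Bile acid transport had 10 of 12 members lower (median -1.27, adjusted p = 0.00093; adjusted p = 0.217 with an estimated correlation). They included the uptake carriers Slc10a1 (-1.59) and Slco1a4 (-4.79), the bile salt export pump Abcb11 (-0.94) and Abcc3 (-2.04). The basolateral exporter Abcc4 rose with 0.77 and the flippase Atp8b1 with 1.59. The receptor and signalling list had a median of -0.14 (adjusted p = 0.615), which was 0.02 under quantile normalization. Within it Nr0b2, a repressor of bile acid synthesis known as SHP, fell with -0.73 (adjusted p = 0.00277). Its activator, the bile acid receptor FXR, encoded by Nr1h4, had -0.20 (adjusted p = 0.0866) and was called when CT 4 was left out (-0.24, adjusted p = 0.0439).

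Cholesterol genes moved in both directions. The synthesis and uptake list had 11 of 25 members lower and 3 higher, with a median of -0.29 (camera adjusted p = 0.0982). The synthesis enzyme Sqle rose with 1.61 (SE 0.148, adjusted p = 4.59e-10), as did Srebf2 (0.36), chosen after its value was seen. Hmgcs1 had 0.44 (adjusted p = 0.0807). It was called without CT 3 (0.53, adjusted p = 0.0343), without C26 7 (0.56, adjusted p = 0.0214) and without C26-CHO 1 (0.44, adjusted p = 0.0295). Sterol efflux genes had a median of -0.16 (adjusted p = 0.208).

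Lipid, drug and amino acid metabolism fell. All 16 genes of fatty acid and triglyceride synthesis fell, among them the transcription factor Srebf1 with -2.59 (median -2.04, adjusted p = 7.89e-09; adjusted p = 0.217 with an estimated correlation). Fatty acid oxidation and ketone synthesis had 14 of 21 members lower, with the peroxisomal enzyme Ehhadh at -2.36 (median -0.66, adjusted p = 0.00056; adjusted p = 0.445 with an estimated correlation). Of the 2 higher members Fgf21 (1.45) was chosen after its value was seen. Phase I drug metabolism had 21 of 22 members lower and Cyp3a13 higher with 2.14 (median -3.94, adjusted p = 2.22e-08; adjusted p = 0.244 with an estimated correlation). Phase II and oxidative stress genes had 16 of 20 lower (median -2.29, adjusted p = 5.79e-06; adjusted p = 0.217 with an estimated correlation). Their 2 higher members, Sult1a1 (0.34) and Hmox1 (1.79), were chosen after their values were seen. Amino acid catabolism and urea cycle genes had 13 of 20 lower (median -0.55, adjusted p = 0.049; adjusted p = 0.493 with an estimated correlation). That call ended without C26-CHO 1 (adjusted p = 0.0867), under quantile normalization (adjusted p = 0.12) and with the replicate number as a block (adjusted p = 0.0643). Glucose metabolism did not pass (median -0.60, adjusted p = 0.0606).

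Hepatocyte identity genes shifted with them. Secreted hepatocyte proteins that fall in the acute phase had 9 of 13 members lower, such as transthyretin, Ttr, with -2.52 and Alb with -2.06 (median -1.21, adjusted p = 0.0203; adjusted p = 0.445 with an estimated correlation). Ambp rose with 1.71, as did Trf (0.71) and Ahsg (0.45, or -0.61 under quantile normalization), both chosen after their values were seen. Pericentral hepatocyte genes, expressed next to the central vein, had 10 of 13 lower and the dicarboxylate carrier Slc13a3 higher with 3.32 (median -0.91, adjusted p = 0.00412; adjusted p = 0.445 with an estimated correlation). Periportal genes had 7 of 14 lower and 6 higher (median -0.15, adjusted p = 0.483). Male-biased liver genes had 13 of 14 lower (median -2.07, adjusted p = 1.85e-05; adjusted p = 0.254 with an estimated correlation), and female-biased genes had a median of -3.34 (adjusted p = 0.125). The growth hormone and IGF axis had a median of -0.09 (adjusted p = 0.248), which was 0.02 under quantile normalization.

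With the preset correlation 19 of 37 lists passed camera, and with an estimated correlation the lowest adjusted p was 0.121. In the exact permutation test of list means per mouse 35 of 37 lists passed, all but erythroid markers (adjusted p = 0.126) and adipocyte markers (adjusted p = 0.751). Counts of members adjusted over the list alone equalled those over all genes in 32 lists. The exceptions were sterol efflux, interferon and erythroid genes (4 higher each in place of 3), iron and metal handling (10 lower in place of 9) and mitochondrially encoded mRNAs (12 lower in place of 11).

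The second comparison, C26-CHO vs C26, asks what cholestyramine changed in the liver of tumour-bearing mice. Genes of bile acid synthesis were higher: Cyp7a1 rose with a log2 fold change of 3.18 (SE 0.608, adjusted p = 0.0157), Cyp8b1 with 2.168 (SE 0.314, adjusted p = 0.00394) and Cyp27a1 with 0.80 (SE 0.159, adjusted p = 0.0208). Cholesterol synthesis and uptake rose as a list, with 12 of 25 members called higher and 0 lower (camera adjusted p = 2.06e-28; adjusted p = 0.118 with an estimated correlation), and so did pericentral hepatocyte genes, with 7 of 13 higher and 0 lower (camera adjusted p = 4.06e-17; adjusted p = 0.0381 with an estimated correlation). Saa3, a serum amyloid gene of inflammation, fell with -1.72 (SE 0.405, adjusted p = 0.0421). Psat1 and Trib3, genes of serine synthesis and of the amino acid stress response, fell with -1.19 and -1.15 (adjusted p = 0.0149 and 0.0208). Of 14040 genes, 99 were called, 78 higher and 21 lower, and 24 of them changed at least 2-fold, 18 higher and 6 lower. An unadjusted p under 0.05 was found for 1832 genes. Leaving out 1 library gave 23 to 273 called genes, and with only these 2 groups in the fit 10 were called. Of the 37 genes named in the text as called in this comparison, 6 kept their call in that fit, namely Cyp8b1, Cyp2c38, Oat, Igfbp2, Dnaic1 and Gm15638 (the last 2 chosen after their values were seen), with adjusted p from 0.0375 to 0.0402. The other 31 did not, with adjusted p from 0.0575 (Srebf2) to 0.114 (Saa3). Saa3 was also not called with the replicate number as a block or in either edgeR test.

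Levels of Cyp7a1 went from 87.1 ± 92.5 in C26 to 1223 ± 2030 in C26-CHO, of Cyp8b1 from 443 ± 230 to 2127 ± 1603, and of Cyp27a1 from 2059 ± 393 to 3754 ± 1672 (mean ± SD, n = 8). Cyp7a1 was above every C26 mouse in 6 of 8 C26-CHO mice, and Cyp8b1 and Cyp27a1 in 7 of 8. C26-CHO 1 had the highest level of each, and the other 7 C26-CHO mice had 511 ± 291, 1593 ± 581.3 and 3198 ± 614.1 in the same order (mean ± SD, n = 7). Without it Cyp7a1 had 2.68 (adjusted p = 0.0156), Cyp8b1 1.92 (adjusted p = 0.00223) and Cyp27a1 0.64 (adjusted p = 0.0156). The call of Cyp27a1 was lost without C26 1 (0.75, adjusted p = 0.0567) and without C26-CHO 7 (0.74, adjusted p = 0.0579). Bile acid synthesis as a list had these 3 of 16 members higher, or 8 higher and 2 lower (Cyp39a1 and Acox2, chosen after their values were seen) adjusted over the list alone. Its median was 0.15 (camera adjusted p = 0.000198; adjusted p = 0.211 with an estimated correlation; exact test of list means, adjusted p = 0.0333). Cyp7b1 had -0.24 (adjusted p = 0.837).

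These genes are protein-coding in GENCODE M21 on GRCm38, and the deposited values are given per gene. Cyp7a1 lies on chromosome 4 at 6265612 to 6275633, Cyp8b1 on chromosome 9 at 121914356 to 121916305 and Cyp27a1 on chromosome 1 at 74713574 to 74737892. Saa3 lies on chromosome 7 at 46711998 to 46715700.

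Bile acid transporters and receptors moved little. Of 12 transport genes the uptake carrier Slco1a4 rose with 1.06 (adjusted p = 0.0258), and adjusted over the list alone Slco1b2, Abcc2 and Abcb4 were higher too and Atp8b1 lower, named here after their values were seen. The list median was 0.20 (camera adjusted p = 0.00554; adjusted p = 0.211 with an estimated correlation; exact test, adjusted p = 0.0827). Slc10a1 had 0.14, Abcb11 0.00, Abcc3 0.26 and Abcc4 -0.10, with adjusted p of 0.623, 0.996, 0.418 and 0.862. None of the 10 receptor and signalling genes was called in the main limma fit (median 0.01, or -0.04 under quantile normalization, camera adjusted p = 0.864). Of these genes Nr1i3, chosen after its values were seen, was called under an alternative. Nr0b2 and Nr1h4 had 0.02 and 0.01 (adjusted p = 0.985 and 0.980).

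**Figure D2:**
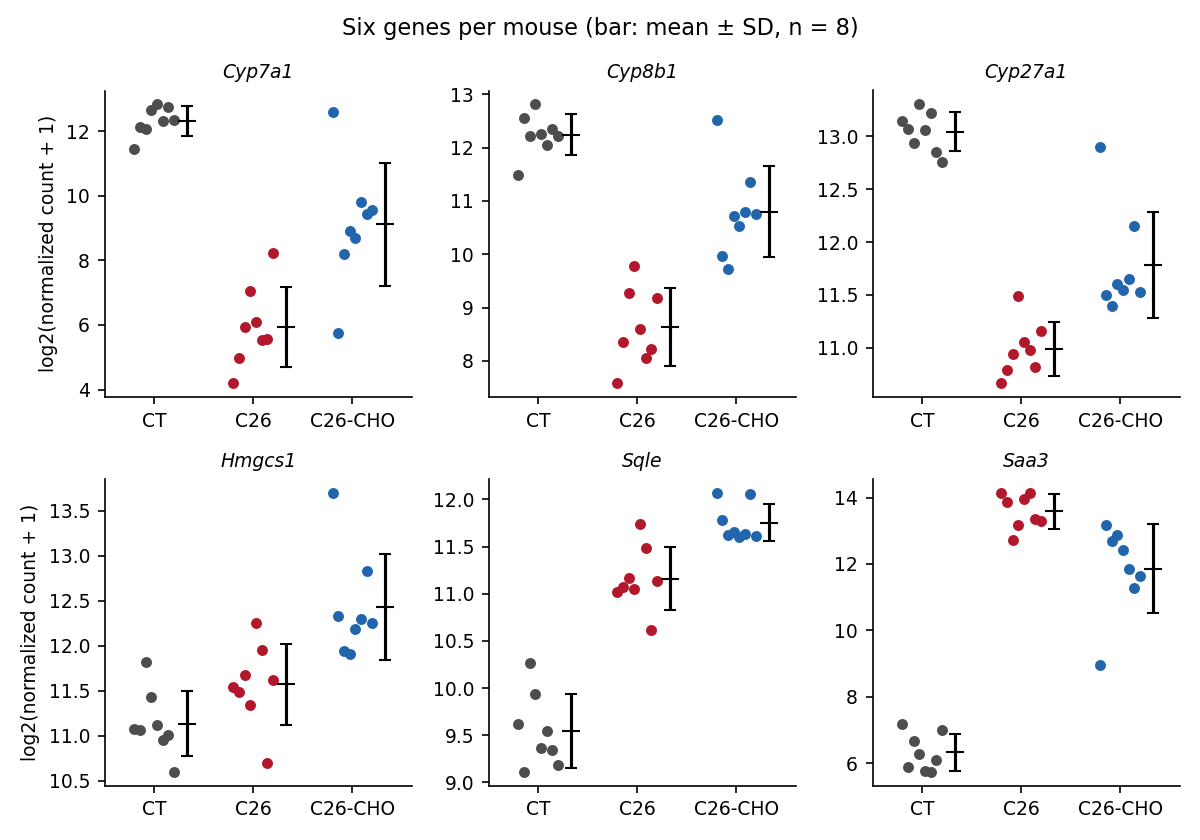
Values of Cyp7a1, Cyp8b1, Cyp27a1, Hmgcs1, Sqle and Saa3 per mouse as log2 of the normalized value plus 1. Points are mice and bars the group mean ± SD, n = 8. The first 3 genes were lower in C26 than in CT and higher again in C26-CHO, with C26-CHO 1 within the CT range, and Hmgcs1 and Sqle of all 8 C26-CHO mice lay above the C26 mean.

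Cholesterol synthesis and uptake had a median of 0.65 (camera adjusted p = 2.06e-28; adjusted p = 0.118 with an estimated correlation; exact test of list means, adjusted p = 0.0144). Adjusted over the list alone, 24 of its 25 members were higher. Srebf2, the transcription factor of the pathway, rose with 0.39 (SE 0.0699, adjusted p = 0.0129) and was above every C26 mouse in 8 of 8 C26-CHO mice. The enzymes Hsd17b7 and Cyp51 rose with 0.65 and 0.83.

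The enzymes Hmgcs1 and Sqle had 0.86 and 0.59 (adjusted p = 0.0628 and 0.0577), with all 8 C26-CHO mice above the C26 mean for each. Hmgcs1 was called without C26 5 (0.96, adjusted p = 0.0362), C26-CHO 3 (0.93, adjusted p = 0.0288) or C26-CHO 4 (0.94, adjusted p = 0.0362). Sqle was called with 0.59 without CT 2 (adjusted p = 0.0495) or CT 3 (adjusted p = 0.0312), and without C26 5 (0.68, adjusted p = 0.024) or C26-CHO 3 (0.61, adjusted p = 0.0393). Both genes were also called under an alternative that left no library out.

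Pericentral genes had a median of 0.58 (camera adjusted p = 4.06e-17), and theirs was the only list call kept with an estimated correlation (adjusted p = 0.0381). Ornithine aminotransferase, Oat, rose with 0.70, the glutamate carrier Slc1a2 with 0.56, the oxidase Gulo with 0.59 and Cyp2c37 with 1.97. All 13 members were higher adjusted over the list alone. The list mean of every C26-CHO mouse was above that of every C26 mouse (exact test, adjusted p = 0.00575). Periportal genes had a median of -0.08 (adjusted p = 0.296).

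Drug-metabolising P450 genes made up most of the largest rises: Cyp2a4 (2.74), Cyp2c38 (2.73), Cyp2c50 (2.45), Cyp2a5 (2.28), Cyp2c54 (2.10) and Cyp2c37, with adjusted p from 0.0129 to 0.0244. The phase I list had 6 of 22 members higher, and 11 adjusted over the list alone. Its median was 0.42 (camera adjusted p = 3.77e-09; adjusted p = 0.211 with an estimated correlation; exact test, adjusted p = 0.0747). Female-biased liver genes had a median of 1.12, with Cyp2a4 called and, adjusted over the list alone, Acot3 also higher and Cyp17a1 lower, both chosen after their values were seen (camera adjusted p = 0.0273; adjusted p = 0.293 with an estimated correlation; exact test, adjusted p = 0.0827). Male-biased genes had a median of 0.08 (adjusted p = 0.183). Phase II genes had Ugt1a1, which conjugates bilirubin, and Gstm2 higher with 0.65 and 0.90, and adjusted over the list alone also Gsta3, Gstm1 and Gclm, chosen after their values were seen (median 0.17, adjusted p = 7.21e-05; adjusted p = 0.211 with an estimated correlation; exact test, adjusted p = 0.147). The difference in phase II list means was 0.336, and 0.195 without C26-CHO 1. Ugt1a1 was not called without C26-CHO 1 (0.57, adjusted p = 0.0564).

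In the growth hormone and IGF axis the binding protein Igfbp2 rose with 1.24 (adjusted p = 0.00558) and the growth hormone receptor, Ghr, with 0.46 (adjusted p = 0.0258). They were the 2 called members of 11, also adjusted over the list alone (median 0.09, camera adjusted p = 0.0557; exact test, adjusted p = 0.0326). Without C26-CHO 1 this list passed camera (median 0.17, adjusted p = 0.0171). Corticosteroid-binding globulin, Serpina6, rose with 1.46 (adjusted p = 0.0129). It was the called member of 13 secreted hepatocyte proteins, joined by Rbp4 and Apoa2, chosen after their values were seen, when adjusted over the list alone (median 0.12, camera adjusted p = 0.00114; adjusted p = 0.211 with an estimated correlation; exact test, adjusted p = 0.0411).

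In fatty acid synthesis the desaturases Fads1 and Fads2 rose with 0.48 and 0.85 (list median 0.28, adjusted p = 1.91e-05; adjusted p = 0.283 with an estimated correlation; exact test, adjusted p = 0.125). The difference in list means was 0.346, and 0.196 without C26-CHO 1. Fads2 was not called without C26-CHO 1 (0.80, adjusted p = 0.0502). Fatty acid oxidation had 0 of 21 members called in the main limma fit, but 16 higher adjusted over the list alone. The list median was 0.28 (camera adjusted p = 3.35e-12, or 0.211 with an estimated correlation, exact test adjusted p = 0.0411). Some alternatives called members, among them Ppara and Acadvl, chosen after their values were seen. In glucose metabolism the gluconeogenic enzyme Fbp1 rose with 0.34, joined by Slc2a2 and Gys2, chosen after their values were seen, when adjusted over the list alone (median 0.09, adjusted p = 0.0465; adjusted p = 0.211 with an estimated correlation; exact test, adjusted p = 0.0671). That list call ended under TMM rescaling (adjusted p = 0.0526) and quantile normalization (adjusted p = 0.0867). Amino acid catabolism had a median and a mean of -0.02 while camera gave the direction up (adjusted p = 0.91), with Oat called, and Asl and Hpd, chosen after their values were seen, also higher adjusted over the list alone.

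**Figure D3:**
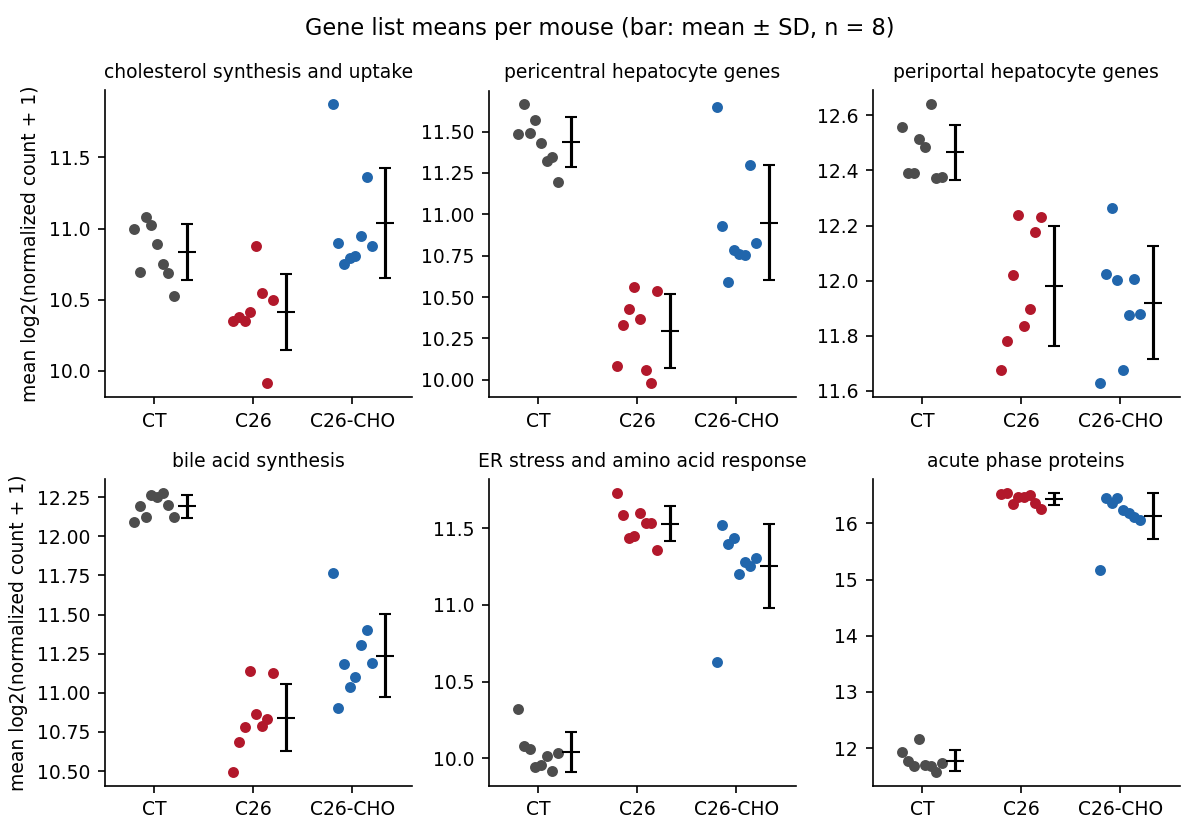
Mean log2 value per mouse of 6 gene lists. Points are mice and bars the group mean ± SD, n = 8. Pericentral means of all 8 C26-CHO mice lie above those of all 8 C26 mice, and C26-CHO 1 has the lowest acute phase mean of its group.

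The acute phase response was largely kept. Saa1, Lcn2 and Socs3 had -0.06, -0.32 and -0.14 (adjusted p = 0.932, 0.524 and 0.740). Saa3 was the called member of 26 acute phase genes, also adjusted over the list alone (median -0.19, camera adjusted p = 2.92e-06; adjusted p = 0.312 with an estimated correlation; exact test, adjusted p = 0.0671). The difference in acute phase list means was -0.304, and -0.168 without C26-CHO 1. The 26 genes took 27.9% ± 3.35 of reads against 30.9% ± 0.912 in C26 (SD, n = 8, exact permutation test, p = 0.00389, adjusted p = 0.0068), with 20.1% in C26-CHO 1. IL-6 and STAT3 genes had a median of -0.05 (adjusted p = 0.220). Complement and coagulation genes had 0.01, or -0.02 under quantile normalization (adjusted p = 0.864). Cytokine and chemokine genes had -0.24, with Cxcl2, Cxcl13, Il1rn and Icam1, chosen after their values were seen, lower adjusted over the list alone (adjusted p = 0.0337; adjusted p = 0.509 with an estimated correlation; exact test, adjusted p = 0.546), a call that ended without C26-CHO 1 (adjusted p = 0.0561) and under quantile normalization (adjusted p = 0.0504). Neutrophil markers were lower too (median -0.78, camera adjusted p = 0.000292; adjusted p = 0.211 with an estimated correlation; exact test, adjusted p = 0.0736).

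Of the ER stress and amino acid response genes Trib3 was called, below every C26 mouse in 8 of 8. Adjusted over the list alone Asns, Ddit3 and Ern1, the last 2 chosen after their values were seen, were lower too (median -0.16, camera adjusted p = 1.91e-05; adjusted p = 0.211 with an estimated correlation; exact test, adjusted p = 0.0333). The other largest falls were the matrix protein Prelp (-0.87), Arhgef2 (-0.78), the growth factor receptor Fgfr1 (-0.69), Tmem268 (-0.59) and the noncoding RNA Zfas1 (-0.51), with adjusted p from 0.0149 to 0.0401. Fgfr1 was not called without C26-CHO 1 (-0.60, adjusted p = 0.0832), with C26 8 left out as well, or in either edgeR test.

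The DESeq2 test on recovered reads called 327 genes in this comparison. Of the 37 lists 18 passed camera with the preset correlation and 7 passed the exact test. Without C26-CHO 1 the exact test passed 3: pericentral genes (adjusted p = 0.0115), cholesterol synthesis and uptake (adjusted p = 0.0287) and the growth hormone axis (adjusted p = 0.0383). With C26 8 left out as well it passed 14. C26 8 had the lowest score of the C26 livers on the first principal component (28.81). Leaving it out was chosen after the data were seen and can widen the difference from C26-CHO.

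The third comparison, C26-CHO vs CT, asks how far the liver of cholestyramine-fed tumour-bearing mice stood from that of control mice. The acute phase list had a median of 4.20 against 4.34 in C26 vs CT. The largest rises were those of Saa2 with 8.96, Lcn2 with 8.65, Saa1 with 8.45, A2m with 7.89, Igdcc4 with 7.51, Orm2 with 7.42, the serine protease Prtn3 with 7.31 and the nicotinamide methyltransferase Nnmt with 7.29. The largest falls were those of Cyp3a11 (-8.69), Car3 (-8.21), Gsta2 (-7.61), Hsd3b5 (-7.29), Gsta1 (-6.76, to 8 reads over all C26-CHO libraries), Ces1f (-6.50), Inmt (-6.46) and Slco1a1 (-6.21). Cyp7a1, Cyp8b1 and Cyp27a1 were still below CT, with -3.20 (SE 0.608, adjusted p = 6.11e-05), -1.44 (SE 0.314, adjusted p = 0.000282) and -1.26 (SE 0.159, adjusted p = 1.7e-07). Called genes numbered 8739, 4395 higher and 4344 lower. At least 2-fold changes were found in 2010 of them, 1113 higher and 897 lower.

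Sterol genes stood on both sides of CT. Sqle was higher with 2.21 (SE 0.148, adjusted p = 1.93e-12), Hmgcs1 with 1.30 (SE 0.218, adjusted p = 1.2e-05) and Srebf2 with 0.75. The list had 12 of 25 members higher and 7 lower (median 0.38, camera adjusted p = 0.295). The carriers Slc10a1, Abcb11 and Abcc3 had -1.46, -0.94 and -1.78, Nr0b2 -0.71, Abcc4 0.67 and Socs3 5.41, each called. Cyp7b1 had -0.68 (adjusted p = 0.0874) and was called without CT 2 (-0.86, adjusted p = 0.0286). Nr1h4 had -0.19 (adjusted p = 0.109) and was called without C26-CHO 1 (-0.26, adjusted p = 0.0201).

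With the preset correlation 16 of 37 lists passed, with an estimated correlation the lowest adjusted p was 0.0914, and 33 of 37 passed the exact test. Acute phase genes had a median of 4.20 in C26-CHO vs CT (25 of 26 higher, camera adjusted p = 5.31e-23; adjusted p = 0.0914 with an estimated correlation). Fatty acid and triglyceride synthesis had -1.51 (16 of 16 lower, adjusted p = 1.27e-08; adjusted p = 0.246 with an estimated correlation), and phase I drug metabolism -3.22 (19 of 22 lower, adjusted p = 3.27e-07; adjusted p = 0.267 with an estimated correlation). Bile acid synthesis had -0.63 (12 of 16 lower, adjusted p = 0.00143; adjusted p = 0.246 with an estimated correlation). These 4 counts were the same adjusted over the list alone. Pericentral genes, which passed in C26 vs CT, had a median of -0.36 and did not pass camera (adjusted p = 0.195), while the exact test found their mean below CT by 0.489 (adjusted p = 0.00663).

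**Figure D4:**
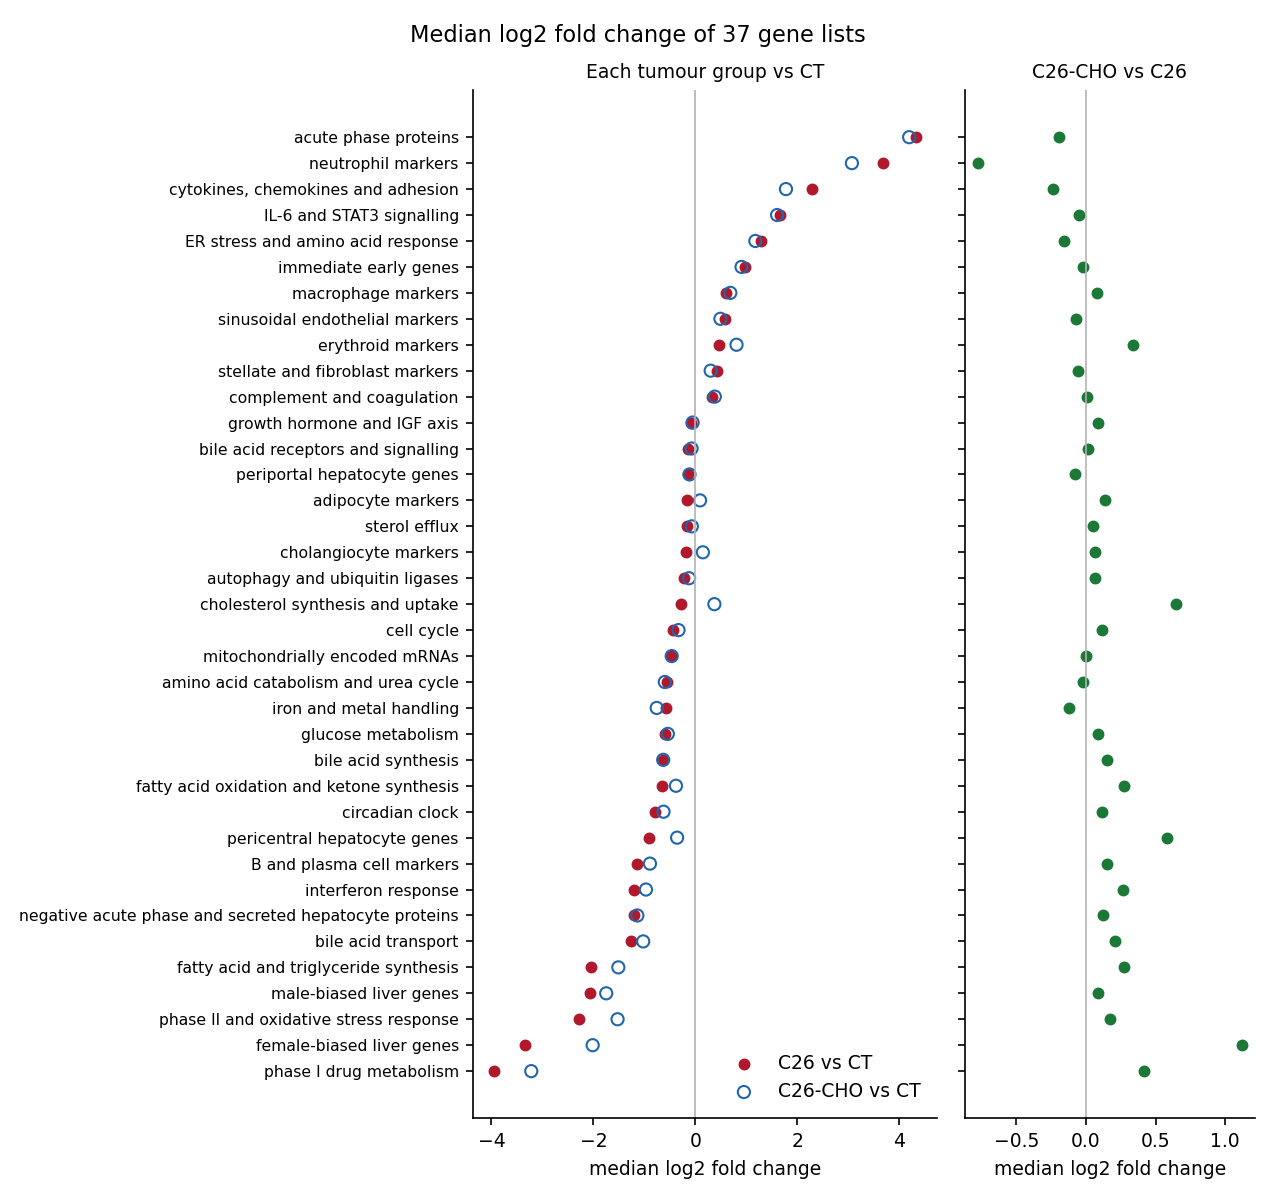
Median log2 fold change of each of 37 gene lists, for both tumour groups against CT (left) and for C26-CHO against C26 (right). Cholesterol synthesis and uptake lies at -0.29 in C26 and at 0.38 in C26-CHO.

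Of the 99 genes called between C26-CHO and C26, 80 moved back, that is, opposite to their change in C26 vs CT. No tumour-free mice received cholestyramine. A loss of the response to the tumour therefore cannot be told apart from an effect of the resin added to that response. Leaving out 1 library gave between 17 (without C26-CHO 7) and 206 (without C26-CHO 3) genes moved back, and the fit of only the 2 groups gave 7. Of the 80, 62 that had fallen were higher and 18 that had risen were lower. Cyp7a1, Cyp8b1 and Cyp27a1 were among those moved up, and Saa3, Psat1 and Trib3 among those moved down. A further 5 genes moved on in the same direction, namely Srebf2, Hacd3, Fam25c, Dnaic1 and Gm15638, and 14 had not been called in C26 vs CT. Of the genes moved back, 62 were still called in the original direction against CT, 17 were not called and 1, the glutamine synthetase gene Glul, was called on the other side (-0.26 in C26 vs CT, or 0.05 under quantile normalization, 0.53 in C26-CHO vs C26 and 0.27 in C26-CHO vs CT). Without C26-CHO 1 Glul had 0.24 in C26-CHO vs CT (adjusted p = 0.0702) and Fam25c 0.75 in C26-CHO vs C26 (adjusted p = 0.0951), neither called. These 6 genes apart from Srebf2 are named after their values were seen.

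The C26 libraries enter both contrasts. Fold changes across genes correlated at -0.583, within the range of simulated unchanged groups (-0.733 to 0.0435, mean -0.505). Their covariance of -0.146 lay below the simulated range (lowest -0.0321, mean -0.0147) and differed from the simulated mean by -0.131. C26-CHO 1, which lay between the groups at -13.41 on the first principal component, enters these values. They were not computed without it. Genes are not independent replicates. Independent lists of these sizes would share 32.7 genes in opposite directions. With C26 divided into replicates 1 to 4 and 5 to 8, the correlations were -0.430 and -0.509, with 2 and 37 genes moved back. In these splits 3 and 48 genes were called in C26-CHO vs C26, and independent lists would share 0.881 and 14.3 in opposite directions. The contrasts of both tumour groups against CT correlated at 0.979 (covariance 0.988), against 0.488 (covariance 0.0142) when simulated, a covariance difference of 0.974. They called 8140 genes in the same direction and 1 in opposite directions, where independent lists would share 2896 in the same direction. With CT divided the correlations were 0.944 and 0.950, with 6547 and 6624 genes in the same direction.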

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

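The 2 tests of C26-CHO 1 below, and the choice of many of the genes looked at, came after the data were seen.

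In 471 groups of 8 values, for genes named in the text and measures of the libraries, 58 had 1 library standing apart from the other 7 (a gap to the nearest other that is a larger share of the range than the 95% critical value of Dixon's ratio). Chance gives about 5% of groups, 1 in 20, and groups of correlated genes are not independent. C26-CHO 1 accounts for 32 of the 58 and C26 8 for 6.

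C26-CHO 1 had the lowest value of its group for genes mostly higher in C26 than in CT: A2m (966.5), Lcn2 (21710), Saa3 (499.3), Reg3b (16.43), Nnmt (3089), Igdcc4 (207.4), Acpp (15.65), Atp6v0a4 (44.61), Osmr (354.5), C3 (499200), Asns (50.09), Mt1 (26530), Mt2 (19370), Slc39a14 (12360), Map1lc3b (3066), Cyp3a13 (1754), Cyp17a1 (69.65) and Sult1a1 (3411). It had the highest for genes mostly lower in C26 than in CT: Car3 (9793), Cyp3a11 (4192), Hsd3b5 (1355), Gsta1 (4.696), Gstm1 (7062), Gstm2 (1415), Slco1a4 (98.61), Dbp (1462), Gabarapl1 (4043), C9 (18080) and mt-Co1 (339600). The acute phase list took 20.1% of its reads, the lowest of the group, mitochondrially encoded mRNAs 4.477%, the highest, and its score on the first principal component was -13.41, the lowest.

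C26-CHO 1 thus lies between CT and the other C26-CHO libraries. RNA of a CT liver mixed into the library would put all genes at 1 share of CT, if this liver otherwise equalled the mean of the other C26-CHO livers. That share had a median of 61.9% over 418 genes that rose at least 4-fold in C26 vs CT. It was 25.9% over 357 that fell, a difference of 36.1 percentage points (95% bootstrap interval 31.6 to 40.6). Mixing into a liver whose own response lay off that mean could also give unequal shares, so mixing is not excluded. Among genes that rose, A2m had 99.6%, Saa3 92.3% and Saa1 16.8%. Among genes that fell, Cyp8b1 had 125.8% and Cyp7a1 118.7%, both beyond the CT mean, Car3 11.1%, Cyp3a11 8.26% and Alb -0.849%. A label swapped with a CT library would leave its acute phase share within the CT range, and it was 8.08 times the highest CT share. A weaker response to the tumour in this mouse, or a stronger one to the resin, stays open and was not tested, since tumour weight and food intake are not given in the sources used here.

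C26 8 had the highest value of the C26 group for Car3 (3742), Cyp3a11 (2392), Ces1f (511.8), Inmt (845.6) and Slco1a1 (848.9) and the lowest for Cxcl1 (5507). Within CT, CT 2 had the highest Cyp2a4 (2211), CT 4 the highest Saa1 (4471), Mt2 (2243) and Fam25c (318.5) and the lowest Cxcr2 (listed at 0), CT 5 the lowest Prtn3 (0.8833) and the highest Slc2a2 (9150), CT 6 the highest Abcc2 (10020), the lowest Spp1 (216.3) and the lowest mitochondrial mRNA share (3.791%), and CT 7 the highest Ctrb1 (1.85). The pancreatic enzyme gene Ctrb1 was also highest in C26 5 (241.1) and C26-CHO 4 (390.6) of their groups. Single values stood apart in C26 1 (Sult1a1, 3790, lowest), C26 3 (Abcb4, 2875, highest), C26 4 (Hamp2, 3953, highest), C26 6 (Thy1, 1.045, lowest), C26 7 (Gulo, 2577, lowest), C26-CHO 3 (Il2rb, 11.11, lowest) and C26-CHO 5 (Mx2, 177.1, lowest).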

How the results depend on the processing

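Leaving out C26-CHO 1 and C26 8 together, leaving out C26-CHO 1 for the gene lists and for every named gene, and the exact test of list means are the tests here that were chosen after the data were seen.

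The counts of C26 vs CT and C26-CHO vs CT stayed within 1.5 times the reported counts under each of the 37 alternatives. Leaving out 1 library gave 9049 to 9399 and 8428 to 8950 genes, and 2402 to 2512 and 1941 to 2185 genes changed at least 2-fold. Quantile normalization reversed 6 fold changes of genes chosen after their values were seen: F11, C26 vs CT (0.00276), Ahsg, C26 vs CT (-0.61), Glul, C26 vs CT (0.0478), Gm42418, C26 vs CT (-0.337), Ahsg, C26-CHO vs CT (-0.469) and Gm42418, C26-CHO vs CT (-0.671). The cause was not tested. Genes called in neither setting changed sign in 95 of 10853 pairs of gene and setting.

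The counts of C26-CHO vs C26 moved more. With only the 2 groups in the fit 10 genes were called, all 10 shared with the reported 99, 5 of them changed at least 2-fold, and 7 genes moved back. The spread is then estimated from fewer libraries, and 1763 genes had an unadjusted p under 0.05 against 1832, but the cause was not tested. DESeq2 called 327 genes (247 higher and 80 lower), which held all 99, with 63 changed at least 2-fold and 257 moved back, and the cause was not tested. edgeR called 117 genes with TMM and 115 with RLE. Other alternatives gave 90 to 112 genes: 95 and 104 with pseudocounts of 0.5 and 5, 90 with no filter, 100 with a mean of at least 50, 102 with TMM rescaling, 108 with quantile normalization (74 higher and 34 lower, against 78 and 21) and 112 with library weights. Leaving out C26-CHO 1 and C26 8 together gave 92 genes, 73 of them shared, and 77 moved back. With C26 divided between the contrasts, 2 genes moved back when replicates 1 to 4 entered the first and 37 when replicates 5 to 8 did, with fewer libraries in each contrast.

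Leaving out 1 library gave 23 to 273 genes, 10 to 52 changed at least 2-fold and 17 to 206 moved back. The count of 99 went to 25 without C26 1, 53 without C26 2, 51 without C26 7, 273 without C26-CHO 3, 160 without C26-CHO 4, 55 without C26-CHO 6, 23 without C26-CHO 7 and 56 without C26-CHO 8. The same libraries moved the 80 genes moved back to 19, 42, 39, 206, 137, 46, 17 and 45. The 24 genes changed at least 2-fold went to 10 without C26 1, 39 without C26 8, 52 without C26-CHO 3, 40 without C26-CHO 4 and 10 without C26-CHO 7. Without C26-CHO 1 72 genes were called, 67 of them shared, 17 changed at least 2-fold and 55 moved back.

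The labels do not say that equal replicate numbers pair the mice. After removal of group means, 9 of 24 pairs of libraries with the same number correlated over 0.1, and 5 of 24 libraries correlated best with one of their own number. With the number as a block 97 genes were called in C26-CHO vs C26, 69 of them shared, with 19 changed at least 2-fold and 73 moved back. Of named genes, Cyp2c54, Saa3, Slco1a4, Ugt1a1, Gstm2 and Ghr lost their call there and Abcc2 and Asl gained one. The list call of amino acid catabolism and urea cycle genes ended in C26 vs CT, and interferon genes gained a call in C26-CHO vs CT.

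In C26-CHO vs C26, calls were also lost by Saa3, Fgfr1 and Cyp2a4 in both edgeR tests, Gstm2 with a pseudocount of 0.5, Gstm2 and Fam25c with no filter, Fam25c with library weights, Fbp1 under quantile normalization, and Fgfr1, Fam25c, Glul and Gm15638 without C26-CHO 1 and C26 8. Of named genes, 89 calls were lost and 73 gained among those 10853 pairs. Of the list calls, the estimated correlation ended 19, 17 and 16 in the 3 comparisons in order, and fry ended 0, 11 and 0 and added 17, 1 and 16. Depth limits genes near the floor: with means under 10 left out, folds of Reg3b, Acpp and Atp6v0a4 rest on 34, 19 and 23 reads over the CT libraries, and that of Mmp8 on 5.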

Other observations

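The exact test of list means, the splits of the mice, the tests without C26-CHO 1, the hepatocyte share test and the bound for the acute phase relation were chosen or reworded after the data were seen.

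Interferon genes, which answer viral and innate signals, moved against the acute phase response. In C26 vs CT 13 of 18 were lower, such as Ifit1 with -2.43, Ifit3 with -2.36 and Rsad2 with -1.95 (median -1.21, camera adjusted p = 0.016; adjusted p = 0.493 with an estimated correlation). Stat2 rose with 0.69, as did Mx2 (0.49) and Zbp1 (1.89), both chosen after their values were seen. In C26-CHO vs C26 the list had a median of 0.27 (adjusted p = 0.00079; adjusted p = 0.409 with an estimated correlation; exact test, adjusted p = 0.116), with 0 of 18 called by limma and Ifit1, with 0.70, higher adjusted over the list alone.

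Metal genes split. The metal-binding proteins Mt2 and Mt1 rose with 6.77 and 5.91 and the zinc and iron importer Slc39a14 with 2.03 in C26 vs CT, while the hepcidin gene Hamp2 fell with -2.85. The list median was -0.58, its mean 0.40 and the camera direction down (adjusted p = 0.273). Circadian clock genes had a median of -0.80 (adjusted p = 0.0982), with the clock activator Arntl at 2.495, the repressor Nfil3 at 1.71 and the clock output Dbp at -3.03. Immediate early genes had a median of 0.98 (adjusted p = 0.243), with Ier3 at 3.64 and Dusp1 at -1.89. Autophagy and ubiquitin ligase genes had -0.21 (adjusted p = 0.125), with Gabarapl1 at -1.48 and Map1lc3b at 1.41. Cell cycle genes had -0.44 (adjusted p = 0.125). In C26-CHO vs C26 the cell cycle median was 0.12 (adjusted p = 0.0382; adjusted p = 0.409 with an estimated correlation; exact test, adjusted p = 0.258), with 0 of 13 called, and without C26-CHO 1 it was 0.08 (adjusted p = 0.238).

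The 13 mitochondrially encoded mRNAs, which code for respiratory chain subunits, took 6.09% ± 1.04 of reads in CT and 3.31% ± 0.196 in C26 (SD, n = 8, exact permutation test, adjusted p = 0.000363). Shares add to a whole, so part of this fall follows from acute phase genes taking 30.9% of C26 reads against 2.18% in CT. In C26 vs CT 11 of 13 were lower, among them mt-Co1 with -0.69 (median -0.47, adjusted p = 0.00956; adjusted p = 0.493 with an estimated correlation). The transcript Gm42418, which overlaps ribosomal RNA sequence, took 0.738% ± 0.197 of reads in CT and 1.16% ± 0.208 in C26 (SD, n = 8, exact permutation test, p = 0.00124, adjusted p = 0.00237). In C26-CHO it took 0.858% ± 0.317, which did not pass against C26 (exact permutation test, p = 0.0434, adjusted p = 0.0607). Quantile normalization turned its direction against CT, to fold changes of -0.337 (Gm42418, C26 vs CT) and -0.671 (Gm42418, C26-CHO vs CT).

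Marker genes of other liver cells moved apart in C26 vs CT. Of 12 listed neutrophil markers 5 passed the level filter, and all 5 rose. Among them were the granule protease Mmp8 with 5.53 (from 5 reads over all CT libraries) and the alarmins S100a8 with 3.89 and S100a9 with 3.68. Their median was 3.68 (camera adjusted p = 0.000858, or 0.235 with an estimated correlation). The filter takes the mean over all 24 libraries, so markers scarce in CT can pass through the tumour groups alone. This favours rises in the count and in the median. Macrophage markers rose in 10 of 12, with the Kupffer cell receptor Vsig4 at 1.02 (median 0.61, adjusted p = 0.00414; adjusted p = 0.485 with an estimated correlation). Markers that did not pass were those of sinusoidal endothelium (0.58, adjusted p = 0.0538, passing under quantile normalization with adjusted p = 0.0436), stellate cells and fibroblasts (0.43, adjusted p = 0.119), B and plasma cells (-1.15, adjusted p = 0.172) and adipocytes (-0.16, adjusted p = 0.984). Cholangiocyte markers had a median of -0.18 and a mean of 0.72 (adjusted p = 0.366), with Spp1 at 4.49 and Sox9 at 3.96. Erythroid markers had a median of 0.47 and a mean of -0.24 (adjusted p = 0.688). In C26-CHO vs C26 neutrophil markers had a median of -0.78, with S100a8, Mmp8 and Cxcr2, the last chosen after its value was seen, lower adjusted over the list alone (adjusted p = 0.000292; adjusted p = 0.211 with an estimated correlation; exact test, adjusted p = 0.0736). Erythroid markers had 0.34 (adjusted p = 0.00509; adjusted p = 0.272 with an estimated correlation; exact test, adjusted p = 0.129).

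Lists too small to test had few members above the level filter. T and NK cell markers had Cd4 with -1.67, Il2rb with -1.34, Gzma with -1.81 and Thy1 with -0.83 in C26 vs CT. Pancreatic acinar markers had Cela1 with -2.55 and Ctrb1 with 0.95 (adjusted p = 0.466), the latter from 2 reads over the CT libraries. Intestinal epithelium markers had Lgals4 with -0.92.

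Lists of metabolic genes were higher in C26-CHO than in C26, and a partial loss of the whole C26 response would raise them too. Against 10000 random lists matched on fold change in C26 vs CT and on mean level, the medians of cholesterol synthesis and uptake and of pericentral genes lay at percentiles 100 and 100, above the bound set for a general loss, while those of bile acid synthesis and phase I drug metabolism lay at 73.8 and 78.6, where a general loss may account for them. Lying outside the matched range is not particular to these lists: 7 of 37 lay above it (also fatty acid oxidation, female-biased, macrophage, erythroid and interferon genes) and 5 below it (iron and metal handling, amino acid catabolism, periportal, male-biased and ER stress genes). Random lists do not carry the correlation between members of a real list, so the range may be too narrow. A list median does not test single members, so the rises of Cyp7a1 and Cyp8b1 were not weighed against a general loss. C26-CHO 1 alone does not account for the rise of cholesterol synthesis and uptake (exact test without it, adjusted p = 0.0287, difference 0.503 against 0.623) or of pericentral genes (adjusted p = 0.0115, difference 0.556 against 0.656), and stays open for bile acid synthesis (adjusted p = 0.0667, difference 0.321 against 0.397) and phase I genes (adjusted p = 0.137, difference 0.601 against 0.844). A higher share of hepatocytes would raise periportal genes alike, but pericentral genes rose more by 0.717 (permutation across genes, p = 2e-05, the smallest these permutations can give). That p treats genes as independent, which they are not, and does not measure the spread between mice. A response to cholestyramine in the first 2 lists stays as a hypothesis, since the pattern was found and tested on the same data.

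The level of Cyp7a1 may follow the strength of the acute phase response within a group, as a hypothesis. Across 8 mice, Spearman correlations with the acute phase list mean were -0.76 in C26 (exact permutation p = 0.0368, adjusted p = 0.0735) and -0.79 in C26-CHO (p = 0.0279, adjusted p = 0.0735). For the cholesterol list they were 0.07 in C26 (exact permutation p = 0.882) and -0.69 in C26-CHO (p = 0.0694, adjusted p = 0.0925). None of the 4 Spearman correlations passed after adjustment, so the relation is left open with 8 mice per group. Pearson correlations for Cyp7a1 were -0.707 in C26, -0.364 without C26 3 and C26 8, and -0.861 in C26-CHO (exact permutation p = 0.00551, adjusted p = 0.022), -0.885 without C26-CHO 1 and C26-CHO 4. For the cholesterol list they were 0.225 in C26 and -0.902 in C26-CHO (exact permutation p = 0.0296, adjusted p = 0.0592), the latter -0.442 without C26-CHO 1 and C26-CHO 4.

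Other splits of the same 16 mice were drawn 100 times per comparison, the real one included. Chance can be excluded for the genes called in C26 vs CT (9305, highest other 7566) and C26-CHO vs CT (8739, highest other 6288), each reached in 1 of 100 splits. The 99 genes called in C26-CHO vs C26 were also reached in 1 of 100 splits (highest other 24), below the bound set for chance, as were the 24 of them changed at least 2-fold (highest other 11) and the 80 moved back (highest other 3). Of 100 simulations of unchanged groups, 1 called at least 99 genes (289, with 9 the next highest), so chance is unlikely for the 99 but not ruled out. The 24 and the 80 are among these 99, so chance is not ruled out for them either. The simulations did not count 2-fold changes. They could hardly give genes moved back, with at most 8 genes called in C26 vs CT. Their genes also lacked differences in mean level, which the trend of the real fit uses. By the splits, chance can be excluded, each with 1 of 100, for genes changed at least 2-fold in the comparisons with CT (2439 against 1687 and 2010 against 1231). The number of lists called by camera did not stay below the bound set for chance. The 19 in C26 vs CT were reached in 13 splits (highest 23). The 18 in C26-CHO vs C26 were reached in 14 (highest 19) and the 16 in C26-CHO vs CT in 18 (highest 23). Splits that mix the groups unevenly keep part of the group difference and can call the same lists. They are not a test of chance alone, so chance stays undecided for these counts. The median of the other splits was 11 lists in each comparison. Camera p with the preset correlation may still overstate the evidence for a list.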
